A study of Homo sapiens with 4 samples.

How the data were processed

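The series measured RNA splicing in MDA-LM2 breast cancer cells with 2 samples transfected with a control siRNA and 2 transfected with siRNAs against SNRPA1. Per the labels' protocols, total RNA was extracted 48 hours after transfection with DNase treatment, and libraries were made with ScriptSeq v2, which marks the strand of the RNA. The design text names 2 independent siRNAs, but the labels do not say which sample received which. STAR 2.7 and the genome build hg38 are named in the submitters' processing notes. Inclusion levels come from MISO, a program that estimates isoform shares from reads, per the file headers. The MISO version, its event annotation, its strand setting and the way the 2 samples of a group were combined are not given in the sources used here.

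The authors deposited, for each group, the inclusion level of every skipped exon event as a fraction from 0 to 1, rounded to 2 decimals, with the lower and upper bound of its interval. The level of that interval is not given in the file headers, so it is called the deposited interval. Per the file headers, each event also has read numbers in 4 classes: reads that fit only the isoform with the exon (inclusion), only the isoform without it (exclusion), both isoforms, or neither. The authors' deposited table of the comparison adds the difference in inclusion level, siSNRPA1 minus siCtrl, and a Bayes factor, the ratio of the evidence for a change to that for no change, which ends at 1e+12. Inclusion levels and read numbers in that table were checked against the 2 group tables and were equal. The group tables list 48092 events for siSNRPA1 and 48574 for siCtrl, of which 47509 are in both. MISO infers the inclusion level from all compatible reads, those in the flanking exons included, so uneven coverage along a transcript can move it without any change in junction reads.

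Events were annotated with GENCODE release 29 on GRCh38, and 45313 of 47509 events had all 4 splice sites in it. A gene was found for 47469 events, and 40 had none. Each exon was placed in coding sequence, a UTR, a transcript annotated as subject to nonsense-mediated decay, or a non-coding transcript. GC content came from the transcript sequences and was found for 94.7% of called exons that fell and 97.7% of those that rose. Splice site strength and the polypyrimidine tract, planned before the data were examined, need intron sequence and were not computed.

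The analysis kept exons with at least 10 inclusion plus exclusion reads in each group and at least 1 read of each kind over both groups, and 1 event per skipped exon, that with the most informative reads, which left 9157. An exon was called with a Bayes factor of at least 10 and an absolute change of at least 0.10 in the authors' deposited table. As each group has 1 deposited value, there is no test across samples. Fisher's exact test, two-sided, was run on inclusion and exclusion reads of the 9157 exons with Benjamini-Hochberg adjustment (adjusted p of at most 0.05 and a change in inclusion read share of at least 0.10). It compares the 2 deposited read sets, not the conditions. Shares have Wilson 95% intervals, and intervals and the floor of 3 counts for a count of 0 cover counting error only, since reads without molecular identifiers are not independent molecules. Gene list medians and features of called exons were placed among 10000 random sets of the same size, matched on informative reads and siCtrl inclusion level in 5 bins each, or on reads alone for read levels. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

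For gene levels, the reads of the event with the most compatible reads were taken for each gene with at least 100 of them over both groups. Ratios are to the sum of compatible reads over all events of each group, in which reads of overlapping events count again, with exact 95% intervals from the 2 counts, and log2 ratios use a pseudocount of 0.5. The median log2 ratio over 7436 genes was 0.00 (0.0032 before rounding). Such reads depend on where the event lies in the transcript and stand in for expression only roughly.

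The 13 gene lists, the thresholds and the rule for named genes were fixed before the data were examined. That rule takes SNRPA1, PLEC and ERRFI1 in any case, the 10 largest falls and 10 largest rises among called exons with at least 20 informative reads in each group and a gene symbol, 1 exon per gene, up to 4 called exons per list, and the 5 highest and 5 lowest read level ratios. Exons called by both the Bayes factor and the exact test, and single genes given as examples of read level within a list, were selected after the values were seen. Some items that the rule takes are not reported here. Alternatives changed the Bayes factor, the change, the read minimum, the choice of event, the interval width and the measure.

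The exact test was tested on simulated reads at the depth of the siSNRPA1 against siCtrl comparison, with 9157 exons. It called 0 of 8957 unchanged exons. With fewer than 100 informative reads it recovered 1 of 82 exons shifted by 1 in log odds and 15 of 81 shifted by 2; with 100 or more reads it recovered 5 of 20 and 15 of 17. The shifted exons were drawn only from those with intermediate inclusion read shares, so recovery at shares near 100% was not measured. An exon that the exact test did not call is therefore not shown to be unchanged.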

Results

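The experiment asked how loss of SNRPA1 alters splicing in MDA-LM2 cells, a human breast cancer line derived from a parent line by selection for growth in the lung. SNRPA1 encodes a protein of the U2 small nuclear ribonucleoprotein, the spliceosome component that binds the intron branch site. Total RNA was taken 48 hours after transfection from 2 samples with a control siRNA (siCtrl) and 2 samples with siRNAs against SNRPA1 (siSNRPA1), and was sequenced after ScriptSeq library preparation. The deposited values hold 1 inclusion level and 1 set of read counts per group for each skipped exon, so no spread between the 2 samples of a group could be measured and no difference below has a replicate check. Summed over the events measured in both groups, the reads that matched at least 1 isoform came to 10071383 in siSNRPA1 and 7497452 in siCtrl. Overlapping events list the same reads again, so these sums are larger than the number of separate reads. Of the sums, 2327494 and 1788136 showed inclusion of the skipped exon, 356167 and 289657 showed its exclusion, and the rest lay in the flanking exons and matched both isoforms. A median of 9 reads per event in siSNRPA1 and 7 in siCtrl told the isoforms apart. Coordinates are on hg38.

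SNRPA1 itself was lower in siSNRPA1. Its event with the most reads, around an 80-nt exon, had 111 reads in siSNRPA1 and 241 in siCtrl. Scaled to all event reads, the level was 34.3% of that in siCtrl (exact 95% interval of the counts 27.1% to 43.1%). Only 19 of 7436 genes with at least 100 event reads had a lower ratio. The 4 SNRPA1 events together gave 28.4% (24.1% to 33.3%), with single events between 14.3% and 55.8%. Of SNRPA1's 4 exons, 2 had no exclusion read in either group and were not compared, and the other 2 did not pass the thresholds for a change in inclusion. The 47-nt coding exon at chromosome 15, 101287656 to 101287702, had inclusion levels of 0.91 in siSNRPA1 and 0.98 in siCtrl, and the 109-nt exon at 101289814 to 101289922 had 0.05 and 0.03. Intervals of read ratios cover counting error only.

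More exons had lower than higher inclusion after SNRPA1 knockdown. Of 9157 skipped exons in 4557 genes with enough reads, 353 exons in 303 genes passed a Bayes factor of at least 10 and a change of at least 0.10 in the authors' deposited table. Inclusion fell in 225 of them and rose in 128, so 63.7% fell (Wilson 95% interval 58.6% to 68.6%). In that table the median change was -0.32 among exons that fell and 0.28 among those that rose, and 284 of the 353 changed by at least 0.20. Over all 9157 exons the median change was 0.00 and the mean -0.0143, with 4535 exons lower, 3638 higher and 984 equal at the 2 decimals of the deposited table. The Bayes factor compares the 2 deposited read sets, not the conditions. When only reads that tell the isoforms apart were counted, Fisher's exact test with Benjamini-Hochberg adjustment called 97 exons, of which 45 fell and 52 rose, and 50 of the 97 were also among the 353 with the same direction. Of the 97, 18 lay in 5′ UTRs, where 1 fell and 17 rose; of the other 79, 44 fell.

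**Figure D1:**
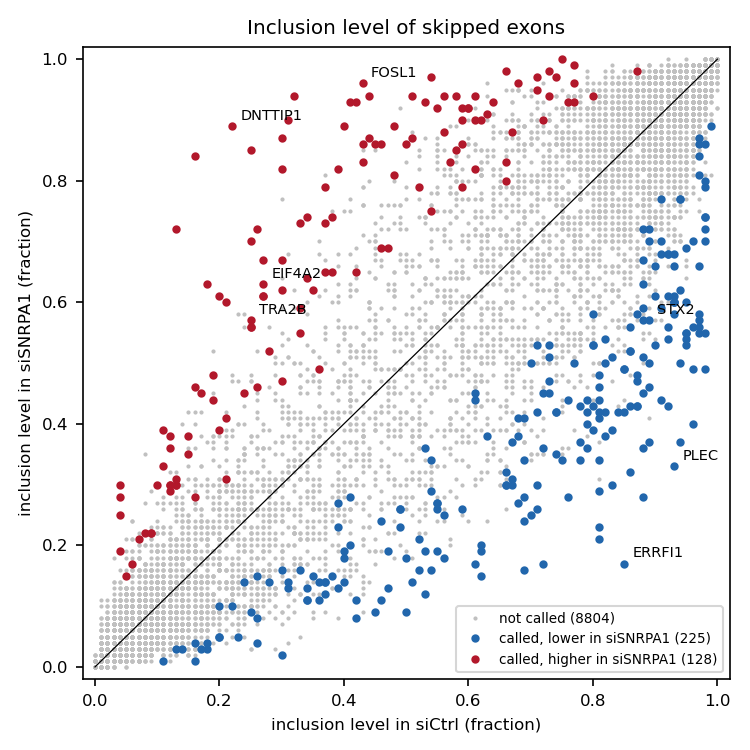
Inclusion level of each of the 9157 skipped exons in siCtrl (x axis, fraction) and in siSNRPA1 (y axis, fraction), 1 point per exon, with the diagonal marking equal levels. The 225 called exons below the diagonal had lower inclusion in siSNRPA1 and the 128 above it had higher inclusion; PLEC and ERRFI1 lie far below the diagonal.

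PLEC and ERRFI1 were among the exons with the largest falls in deposited inclusion level. PLEC encodes plectin, a large protein that links intermediate filaments to other parts of the cytoskeleton and to adhesions, and ERRFI1 encodes an inhibitor of the epidermal growth factor receptor. The PLEC exon is a 3381-nt coding exon, number 31 of its transcript, at chromosome 8, 143922504 to 143925884. Its inclusion level was 0.33 (deposited interval 0.32 to 0.34) in siSNRPA1 and 0.93 (0.91 to 0.95) in siCtrl. The ERRFI1 exon is the 77-nt coding exon 3 at chromosome 1, 8015308 to 8015384, with levels of 0.17 (0.12 to 0.23) and 0.85 (0.72 to 0.95). A longer 93-nt form of this exon had levels of 0.16 and 0.69. The authors' deposited table gives both genes a Bayes factor of 1e+12.

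Reads across the exon-skipping junction were rare at both exons in both groups. PLEC had 5238 inclusion and 7 exclusion reads in siSNRPA1 and 7470 and 32 in siCtrl, so inclusion reads made up 99.9% and 99.6% of them. Fisher's exact test, which compares the 2 deposited read sets, gave p = 0.00294 in the direction opposite to the inclusion level (adjusted p = 0.142). Scaled to depth, PLEC inclusion reads were 0.522 times the siCtrl level (0.504 to 0.541) while reads in its flanking exons were 1.61 times (1.58 to 1.64). ERRFI1 had 30 inclusion and 0 exclusion reads in siSNRPA1 and 135 and 1 in siCtrl. Its scaled inclusion reads were 0.165 times the siCtrl level (0.107 to 0.247) and its flanking reads 0.905 times (0.873 to 0.938). The share of inclusion reads was 100% in siSNRPA1 (Wilson 95% interval from 88.6%) and 99.3% in siCtrl (96.0% to 99.9%), so these reads showed no gain in skipping, and only a gain within that interval was not detectable at this depth.

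The other largest falls lay in genes of varied function. STRN3, a subunit of a phosphatase and kinase complex, went from 0.88 in siCtrl to 0.28 in siSNRPA1 at its 111-nt coding exon (chromosome 14, 30929201 to 30929311). GIGYF2, a translational repressor, went from 0.81 to 0.21 at a 66-nt exon in the 5′ UTR (chromosome 2, 232703424 to 232703489). Inclusion also fell in DCAF7 (0.96 to 0.40), the histone methyltransferase gene KMT5A (0.83 to 0.30), EFTUD2, a core protein of the U5 particle (0.92 to 0.43), ATP5F1C, a subunit of mitochondrial ATP synthase (0.98 to 0.49), and TAMM41 (0.62 to 0.15). AC087632.1, a readthrough gene that shares its exons with PCLAF, went from 0.94 to 0.37, and its reads cannot be assigned to 1 of these genes. Of these exons, only that of TAMM41 was also called from exclusion and inclusion reads, with 9 inclusion and 22 exclusion reads in siSNRPA1 against 16 and 4 in siCtrl (Fisher's exact test, adjusted p = 0.0427). STRN3 had 1 exclusion read in siSNRPA1 and 0 in siCtrl. DCAF7 had 43 inclusion and 0 exclusion reads in siSNRPA1 and 151 and 2 in siCtrl, so its inclusion read share moved against the fall.

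The largest rise was in DNTTIP1, part of a histone deacetylase complex, where a 99-nt coding exon (chromosome 20, 45795345 to 45795443) went from 0.22 (0.15 to 0.31) to 0.89 (0.75 to 0.98). Rises followed in AGPAT2, an enzyme of phospholipid synthesis (0.32 to 0.94), UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex (0.30 to 0.87), and FOSL1, an AP-1 transcription factor subunit (0.43 to 0.96). The metalloprotease gene ADAM9 (0.41 to 0.93), LETMD1 (0.30 to 0.82), SRRT (0.42 to 0.93), the malate dehydrogenase gene MDH2 (0.44 to 0.94), the microtubule-associated MAP4 (0.26 to 0.72) and DERL2 (0.25 to 0.70) completed the 10 largest. Each of these 10 exons had at most 3 exclusion reads in either group, and Fisher's exact test on reads called none of the 10. The inclusion read share moved slightly against the rise in DNTTIP1, UBE2C, FOSL1, ADAM9 and SRRT and slightly with it in the others.

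**Figure D2:**
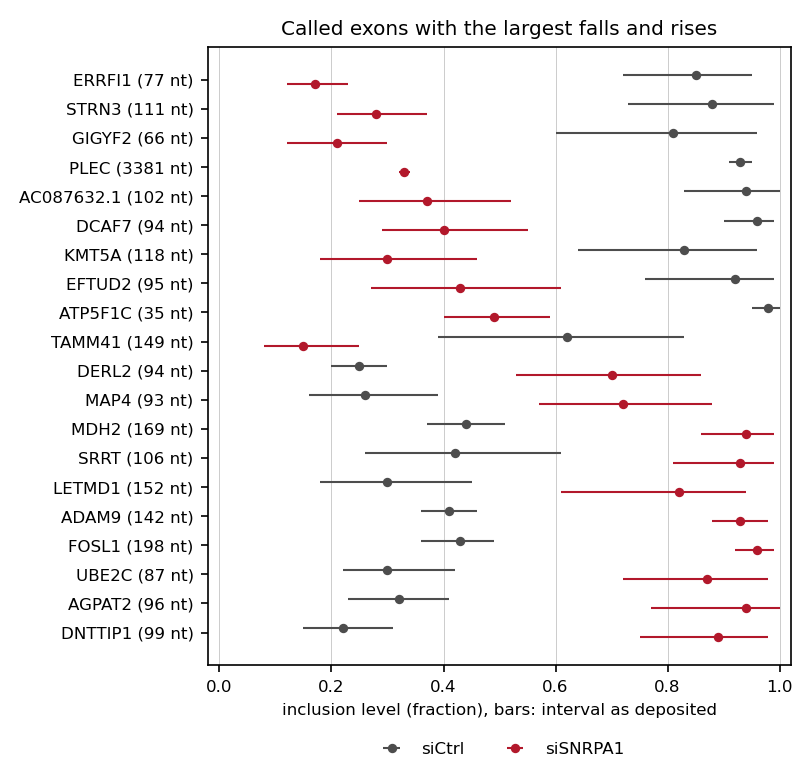
Inclusion level (x axis, fraction) of the 10 called exons with the largest fall and the 10 with the largest rise, 1 exon per gene and at least 20 informative reads per group; points are the deposited levels of siCtrl and siSNRPA1 and bars their deposited intervals. PLEC has the narrowest interval, 0.32 to 0.34 in siSNRPA1.

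A second set of exons, selected after their values were seen, passed both the Bayes factor and the exact test on reads in the same direction: 33 fell and 17 rose, with SMN1 and SMN2 counted separately. EIF4A2, an RNA helicase of translation initiation, had the clearest read support. Its 111-nt exon (chromosome 3, 186788310 to 186788420, annotated only in a non-coding transcript) had 557 inclusion and 125 exclusion reads in siSNRPA1 and 240 and 198 in siCtrl. Inclusion reads rose from 54.8% (Wilson 95% interval 50.1% to 59.4%) to 81.7% (78.6% to 84.4%), and the deposited level from 0.27 to 0.63 (Fisher's exact test, adjusted p = 7.55e-18). Inclusion reads also rose in CD151, a tetraspanin (50.8% to 84.2%), PUF60, a splicing factor that acts with the U2 particle (37.5% to 62.2%), UBE2D2 (43.2% to 71.8%), ZNF207 (33.3% to 70.5%), PPP6R3 (23.0% to 56.1%), SDCBP (69.4% to 90.5%), PCNX4 (11.4% to 46.3%) and the antisense RNA gene ZSCAN16-AS1 (56.7% to 92.5%). PSMA1 went from 47.9% to 72.0%, with reads that may not be separable from the overlapping AC018523.2.

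Inclusion reads fell in the casein kinase gene CSNK1A1 from 84.6% (80.7% to 87.8%) to 64.9% (60.6% to 69.1%) at an 84-nt coding exon (chromosome 5, 149517794 to 149517877; Fisher's exact test, adjusted p = 3.87e-08). They also fell in the syntaxin gene STX2 (91.4% to 66.7%), the RNA-binding protein gene TIAL1 (90.2% to 69.3%), the scaffold gene DLG1 (91.0% to 68.5%), the phosphatase gene PTPN3 (92.0% to 63.8%) and ARSJ (63.2% to 15.2%). RABGGTB went from 92.2% to 78.5% at an exon that overlaps ACADM. SMN1 and SMN2 both went from 95.6% to 72.0% with the same counts, 103 inclusion and 40 exclusion reads against 108 and 5. These near-identical paralogs share reads, so the change cannot be assigned to either.

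**Figure D3:**
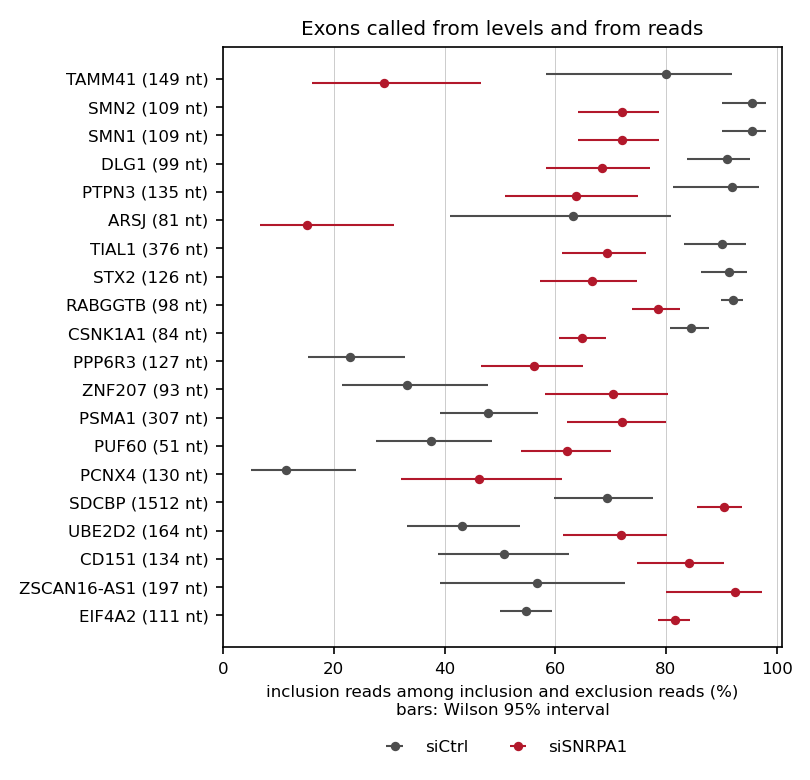
Share of inclusion reads among reads that tell the isoforms apart (x axis, percent) in siCtrl and siSNRPA1 for the 10 largest falls and 10 largest rises, by deposited level, among exons called by both criteria; bars are Wilson 95% intervals. EIF4A2 moved from 54.8% to 81.7% and CSNK1A1 from 84.6% to 64.9%.

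Among gene lists fixed before the data were examined, genes of RNA splicing had changes in both directions. For U2 particle and branch-site proteins, 25 exons in 13 genes were measured, 1 fell, 1 rose and 23 did not pass. SF1, which binds the branch site before the U2 particle, went from 0.20 to 0.05 at a 205-nt coding exon, and PUF60 from 0.26 to 0.46 at a 51-nt coding exon. Of 81 exons in other core spliceosome genes, EFTUD2 and PPIL3 (0.76 to 0.28) fell, PRPF18 (0.09 to 0.22) and SNRPE (0.04 to 0.25) rose, and 77 did not pass. SNRPE had 65 inclusion and 2 exclusion reads in siSNRPA1 and 16 and 0 in siCtrl, so its read share moved against the level. Of 58 exons of SR proteins and their kinases, 3 fell and 1 rose. RNPS1 went from 0.93 to 0.60, RSRC1 from 0.76 to 0.44 and SON from 0.23 to 0.05, whereas the 276-nt exon of TRA2B found only in transcripts subject to nonsense-mediated decay went from 0.25 (0.20 to 0.31) to 0.57 (0.51 to 0.63). Among hnRNPs and other splicing regulators, 9 of 143 exons fell and 2 rose, including PTBP1 (0.84 to 0.42 at a 57-nt coding exon and 0.93 to 0.61 at its 78-nt form) and TIAL1 (0.50 to 0.18 at a 376-nt exon found only in decay transcripts). The exact test called 2, 3, 1 and 5 exons of these 4 lists over all exons and 4, 3, 3 and 7 when adjusted over the list alone. Of those called over all exons, 1, 0, 0 and 5 were also called by the Bayes factor. The hnRNP list's median change in inclusion read share was -0.638 percentage points (percentile 1.30 of matched random lists), against percentile 13.8 for its median inclusion level.

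In genes of cell adhesion, the cytoskeleton and epithelial-mesenchymal transition (EMT), most of the few called exons fell. Most called exons also fell over all genes (63.7%), where 3.85% of exons were called. In genes with EMT-associated cassette exons, 6 of 165 exons fell and 0 rose, among them ATP5F1C, STX2 (0.89 to 0.57), the p120-catenin gene CTNND1 (0.36 to 0.14 at a 289-nt exon that also overlaps AP001931.1) and SEC31A (0.61 to 0.44). The exact test called 7 exons of this list over all exons and 8 adjusted over the list alone. In cytoskeleton and adhesion genes, 7 of 157 exons fell and 2 rose. Besides PLEC and MAP4, the fixed rule took SORBS2 (0.79 to 0.36) and ABI1 (0.80 to 0.43). The list median was -0.01 in both lists, at percentile 4.53 of 10000 matched random lists for EMT genes and 2.53 for cytoskeleton genes. By inclusion read share the medians lay at percentile 7.54 for EMT genes and 43.2 for cytoskeleton genes. The exact test called 1 cytoskeleton exon over all exons and 2 adjusted over the list alone.

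Cell cycle and mitosis genes had 8 exons that fell and 1 that rose among 142. The centromere histone CENPA went from 0.78 to 0.37, the cohesin subunit SMC1A from 0.55 to 0.19, cyclin B1 (CCNB1) from 0.97 to 0.66, and the spindle protein NUSAP1, which overlaps AC087721.2, from 0.83 to 0.51. CCNB1 had 0 exclusion reads in siSNRPA1 and 1 in siCtrl. The exact test called 3 exons of this list over all exons and 4 adjusted over the list alone. Of 54 apoptosis exons, 3 fell and 2 rose, and the rule took the inhibitor gene XIAP at 2 exons (0.71 to 0.26 in the 5′ UTR and 0.73 to 0.94 in the coding sequence), BCL2L12 (0.87 to 0.43) and survivin (BIRC5, 0.41 to 0.28). Of 121 DNA damage repair exons, BARD1 fell (0.97 to 0.58) and XPA (0.21 to 0.60), BRIP1 (0.17 to 0.45) and XRCC6 (0.30 to 0.47) rose. In receptor and kinase signalling, 3 of 92 exons fell, namely both ERRFI1 forms and the focal adhesion kinase gene PTK2 (0.89 to 0.70), and SMAD2 rose (0.19 to 0.48). The exact test called 1 apoptosis exon and 0 in the DNA repair and signalling lists, with the same numbers adjusted over the list alone. In interferon and RNA sensing genes, 2 overlapping IFI44 exons rose (0.64 to 0.93 and 0.43 to 0.83) and 21 did not pass. None of 13 exons of p53 and stress response genes passed. The medians of these 6 lists lay between percentiles 57.4 and 83.4 of matched random lists, and the 4 splicing lists between 6.07 and 55.3. Of the 55 called exons that the fixed rule named, the exact test on reads called 5, and in 15 the share of inclusion reads moved against the inclusion level. Among the 15 are CCNB1, both ERRFI1 forms, XRCC6, SMAD2 and both IFI44 exons. XRCC6 had 662 inclusion reads and 1 exclusion read in siSNRPA1 and 407 and 0 in siCtrl. BARD1 had 1 exclusion read in siSNRPA1 and 0 in siCtrl.

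Called exons differed from matched exons in intron length, base composition and transcript class. Exons that fell followed shorter introns, with a median of 1415 nt against 2342 nt in matched random sets (percentile 0.01), and exons that rose followed longer ones, 3413.5 nt against 1931 nt (percentile 99.96). Exon GC content was 49.0% in exons that fell (matched 47.1%, percentile 99.5) and 44.4% in exons that rose (matched 47.5%, percentile 0.085). Exons found only in transcripts subject to nonsense-mediated decay made up 17.8% of falls against 8.44% in matched sets (percentile 100), and 10.2% of rises against 16.4% (percentile 1.63). For rises this was inside the central 95% with a change of at least 0.20 (percentile 7.32) and with the exact test (percentile 3.57). Coding exons made up 56.4% of falls (matched 70.7%) and 60.2% of rises (matched 51.6%). For exons called by the Bayes factor, exon length and the share of exons divisible by 3 lay inside the central 95% of matched sets in both directions. The percentiles describe these 2 read sets, since exons are not replicates. Among exons called from reads, exon GC content was not set apart (percentile 80.1 for falls and 86.2 for rises). Coding exons made up 42.2% of these falls (matched 55.6%) and 28.8% of these rises (matched 34.6%, percentile 20.8), and rises had a median length of 177.5 nt against 130.5 nt (percentile 99.9). In this set the upstream intron was again shorter before falls (999 nt, percentile 0.88) and longer before rises (3069.5 nt, percentile 98.4), and the downstream intron was also shorter for falls (1118 nt against 2044 nt, percentile 0.76).

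Event reads also served as a rough measure of each gene's level. Interferon and RNA sensing genes had a median log2 ratio of 0.37 (1.29 times siCtrl, percentile 99.9 among 10000 random lists of 19 genes). For 10 of the 19 the interval lay above 1 and for 2 below 1. Over all 7436 genes it lay above 1 for 1986 and below 1 for 1961, so such an interval is common between these 2 read sets. IFI27 had the highest ratio of all 7436 genes, 8.11 times (5.58 to 12.2; 327 against 30 reads). IRF9, an interferon regulatory factor, was 2.16 times higher (1.72 to 2.73), whereas IFI44 was 0.528 times (0.467 to 0.596). Genes with EMT-associated exons (median log2 ratio 0.27, percentile 99.99), cytoskeleton and adhesion genes (0.24, percentile 99.99) and hnRNPs and other splicing regulators (0.20, percentile 99.7) also stood above matched lists. The 95% interval of the list median, from its order statistics, was 0.065 to 0.395 for cytoskeleton genes, and it included 0 for the interferon (-0.008 to 0.966), EMT (-0.006 to 0.406) and hnRNP (-0.038 to 0.395) lists. Examples are the actin gene ACTB (1.96 times, 1.91 to 2.02), the actin crosslinkers ACTN1 (2.34 times, 2.19 to 2.49) and FLNA (1.75 times, 1.68 to 1.83), and the RNA-binding protein PCBP2 (4.17 times, 3.67 to 4.77). MATR3 went the other way (0.414 times, 0.395 to 0.432).

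Cell cycle genes had a median log2 ratio of -0.11 (interval -0.234 to 0.074, percentile 0.78). Intervals lay below 1 for 35 of 82 genes and above 1 for 20, beside 1961 and 1986 of all 7436 genes. CDC25B (0.460 times, 0.412 to 0.514), CDC25C (0.415 times, 0.307 to 0.557) and CDCA5 (0.413 times, 0.368 to 0.463) were lower and MKI67 (1.81 times, 1.67 to 1.96) was higher. The other 8 lists lay inside the central 95% of random lists. They include the U2 list, in which SF1 had a log2 ratio of 1.43, and the SR list, in which SRRM2 was 3.47 times higher (3.33 to 3.61). After IFI27, the highest ratios were those of RUNX1 (4.99 times, 3.10 to 8.43), PCBP2, GATAD2B (3.93 times, 2.74 to 5.78) and SRRM2. The lowest were those of TMEM138 (0.178 times, 0.132 to 0.237), CD99 (0.209 times, 0.141 to 0.303), GLRX3 (0.225 times, 0.170 to 0.293), NDFIP2 (0.224 times, 0.160 to 0.309) and GTF2H2B, a copy of GTF2H2 whose reads may be shared between copies (0.253 times, 0.206 to 0.310). PLEC was 1.26 times and ERRFI1 0.887 times the siCtrl level. Of 26 markers of immune, endothelial and luminal breast cells, only KRT8 (1.32 times, 1.22 to 1.42) and ESRP2 (1.28 times, 0.868 to 1.91) had 100 event reads, and no exon of these genes passed the read minimum. These ratios rest on 1 event per gene and 1 value per group, so they are no test of expression.

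**Figure D4:**
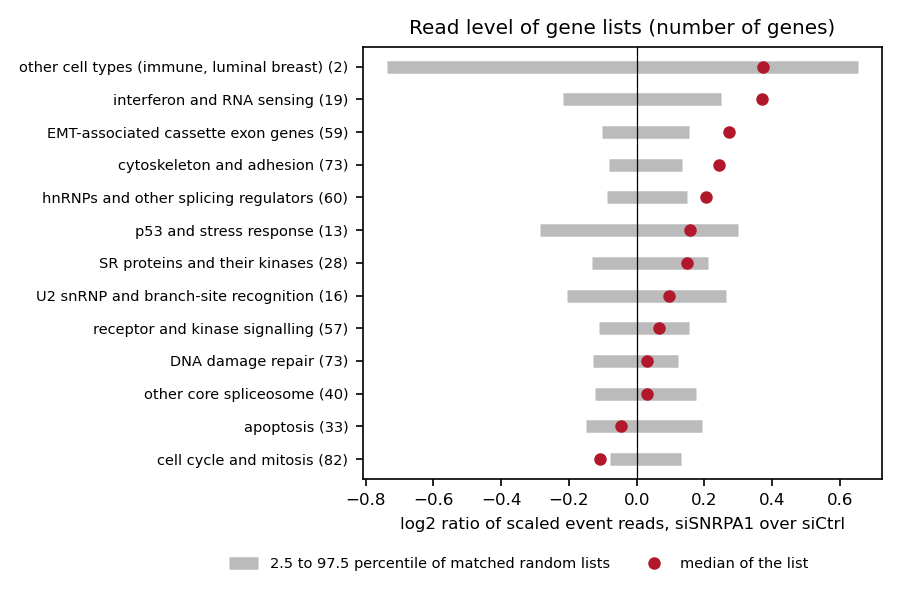
Median log2 ratio of scaled event reads, siSNRPA1 over siCtrl (x axis), for the 13 gene lists, with the number of genes in brackets; grey bars span the central 95% of 10000 random lists of the same size matched on reads. The interferon, EMT, cytoskeleton and hnRNP lists lie above their grey bars and the cell cycle list lies below its bar.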

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

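The tests of exclusion reads, of conflicting reads, of GC content and of exons called from reads alone were chosen after the results were seen; the test of exons before a last exon and that of depth were written down before their values were known, except the interval of the difference in the former.

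An event outside the comparison was listed for siSNRPA1 alone. A 144-nt coding exon of WDR90 (chromosome 16, 666455 to 666598), a gene of cilia and centrioles, had 27 compatible reads in siSNRPA1, of which 11 showed inclusion and 0 exclusion, and was absent from the siCtrl table. No listed event has fewer than 20 reads of all classes, so fewer reads of it in siCtrl are not excluded. In all, 583 events were listed for siSNRPA1 alone and 1065 for siCtrl alone, the latter with up to 26 compatible reads.

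Reads that matched neither isoform of an event entered no comparison of inclusion. Their share was higher in siSNRPA1 with non-overlapping Wilson 95% intervals in 553 genes and lower in 1691. The largest gains were in the ribosomal protein gene RPS10 (83.4% against 49.8%), the small nucleolar RNA host gene SNHG6 (74.2% against 43.5%) and CD99 (82.4% against 55.1%), the gene with the second lowest read level ratio.

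Many called exons had few exclusion reads: 129 of the 353 had at most 3 over both groups, and 54.1% of their 222 exclusion reads lay in the group with the lower inclusion level (Wilson 95% interval 47.5% to 60.5%). Reads simulated with no change in skipping gave 51.8% to 64.9%, and with the least change that the deposited intervals allow 61.3% to 73.0%. This argues against skipping by the deposited amounts in this set only. The set was picked for few exclusion reads, which leaves out exons with more of them, so it says nothing about the other called exons. Loss of reads from GC-rich exons stays open: of the 192 called falls with a GC value, 98.4% kept a fall of at least 0.10 without the GC trend, but that trend ran only from -0.01 to 0.00 and so decides nothing. Coverage rising towards the 3′ end would make more exons before a last exon fall, yet fewer did, 53.4% against 65.8% of the others. This explanation stays open because the difference of -12.3 percentage points has an interval that includes 0 (Newcombe 95% interval -26.0 to 1.1). Exons that rose in the exact test were more often before a last exon (30.8% against 17.3% in matched sets, percentile 99.2). That test leaves out reads of the flanking exons, so it cannot decide this question. ERRFI1 in siSNRPA1 had a level of 0.17 with 30 inclusion, 0 exclusion and 6716 reads of both isoforms. FOSL1 in siCtrl had 0.43 with 164, 0 and 2721. Such levels do not follow from inclusion and exclusion reads alone. How far flanking reads set the levels of the other called exons stays open. Of 28 called exons taken as able to show a conflict with the deposited level, 4 did (14.3%, 5.7% to 31.5%). Among all 353, 8 did (2.3%). The 28 thus leave out exons that showed a conflict, and their share decides nothing.

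More called exons fell than rose, 225 against 128. Lower depth in siCtrl, which would pull high levels down there, is argued against, since 65.9% of called exons with a mean level above 0.5 fell (59.2% to 71.9%). The way the inclusion level is estimated stays open: among exons called from inclusion and exclusion reads alone, 46.4% fell (36.8% to 56.3%), but without exons in 5′ UTRs 55.7% of 79 fell (44.7% to 66.1%), a range that holds the 63.7% found with the deposited levels. Reads alone also showed a small net fall in the mean, with a change in inclusion read share of -0.588 percentage points over all exons. Redrawn reads gave -0.147 to 0.114, a range that covers counting error only. The median change in share was -0.394 percentage points, and 0 when both groups were thinned to the same depth per exon. Loss of SNRPA1 as the cause of a net fall also stays open and has no replicate check.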

How the results depend on the processing

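Of the alternatives, 2 on exons called by both criteria and on exons without conflicting reads, 1 that kept 1 exon per gene and 1 without exons in 5′ UTRs were chosen after seeing the data. The number of called exons, 353, became 193 with a Bayes factor of at least 100, 720 with no read minimum, 185 with at least 50 informative reads, 184 with both intervals at most 0.25 wide, 97 with the exact test on reads, 79 with that test without 5′ UTR exons and 50 with both criteria in the same direction. With a stricter threshold the count falls by construction; with no read minimum 346 of the 353 exons were shared, and for this setting and the exact test with all exons the cause was not tested. The share that fell stayed between 58.7% and 66.0% under all alternatives that use the deposited levels and was 46.4% with the exact test, which turns its direction, and 55.7% with that test without 5′ UTR exons, which does not. Reads redrawn with no change between the groups gave 0 calls by the adjusted exact test in each of 20 draws. Among exons at an unadjusted exact p under 0.05, 48.8% fell (median of the draws, 42.1% to 52.8%) against 55.4% observed. The draws hold counting error only, so they cover neither the spread between samples nor the calls by the Bayes factor. SNRPA1 read level, the median change over all exons, and 56 of 57 alternatives for gene list medians and exon features stayed within the 95% interval of the main value. Many of the 57 could hardly move: rescaling shifts list read levels by 0.0032 only, and the feature alternative keeps 284 of the same 353 exons. Features of exons called by the exact test are not among the 57, and several lay outside that interval. Its rises had a median length of 177.5 nt (main interval 122 to 162), and 28.8% were coding (51.5% to 68.2%). With a change of at least 0.20, 2 features of rises left the outer 5% of matched sets. These were the share in decay transcripts and exon GC minus flanking GC (percentiles 7.32 and 6.78). The SR protein list's median went from 0.00 to 0.0009 with read shares. Of the 55 called exons that the fixed rule named, 15 changed direction with the share of inclusion reads, 35 kept it but were not called by the exact test and 5 were called; 13 were no longer called with a Bayes factor of at least 100, 26 with 50 reads, 26 with narrow intervals and 7 with a change of 0.20. The 15 changes in share, in percentage points, were 0.29 for PLEC, 0.74 and 0.78 for ERRFI1, 1.31 for DCAF7, 0.07 for CCNB1, -0.39 for FOSL1, -2.33 for SMAD2, -2.99 for SNRPE, -1.53 and -1.79 for IFI44, -1.3 for DNTTIP1, -0.69 for UBE2C, -0.15 for XRCC6, -1.39 for SRRT and -0.14 for ADAM9; the cause was not tested. No paired analysis was possible because each group has 1 deposited value, and for the same reason no replicate could be left out.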

Other observations

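The test of repeated genes and that of unspliced reads were written down before their values were known, after the pattern had been seen.

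Exons in 5′ UTRs had a higher share of inclusion reads in siSNRPA1. Over 1182 such exons the mean change in inclusion read share was 1.81 percentage points, against -0.95 to 0.35 in matched exon sets. Of the 18 that the exact test called, 17 rose, among them exons of PRKAG1, a subunit of the energy sensor AMPK (27.4% to 60.3%), the cohesin subunit STAG2 (20.8% to 51.1%), the co-chaperone DNAJB6 (5.54% to 23.5%), the elongation factor EEF1D and the tetraspanin CD151. The exception was ANXA2, a membrane-binding annexin, which went from 26.4% to 15.1% (172 inclusion and 970 exclusion reads against 653 and 1816). The deposited inclusion levels of the same 1182 exons did not stand apart, with a mean change of -1.06 percentage points against -1.48 to -0.35 in matched sets.

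Several exons of 1 gene, as in EEF1D, do not account for this direction: with 1 exon per gene, 91.7% of 12 genes rose (Wilson 95% interval 64.6% to 98.5%). The share can rise through more inclusion reads or through fewer exclusion reads. PRKAG1 had 41 inclusion and 27 exclusion reads in siSNRPA1 against 20 and 53 in siCtrl. STAG2 had 23 and 22 against 25 and 95. Exclusion reads were lower in siSNRPA1, before scaling, in each called 5′ UTR exon that rose and also in ANXA2, which fell. Over all events they were higher in siSNRPA1 (356167 against 289657). Reads of unspliced RNA inside these exons remain a candidate source of added inclusion reads, but would not lower exclusion reads. Reads that match neither isoform gained over compatible reads by a median log2 of 0.205 in the 18 exons. This gain was inside the range of -0.315 to 0.237 of matched sets but above their median of -0.054. As sources of added inclusion reads, unspliced RNA and a change in splicing or in the transcription start therefore cannot be told apart for these exons.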
